A study of Homo sapiens with 32 samples.

How the data were processed

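RNA was measured in 32 libraries from 4 human prostate cancer cell lines, in 16 groups of 2 libraries. The labels give total RNA extracted with a Direct-Zol kit, an Illumina instrument and cells from ATCC. In the knockdown experiment LNCaP, C4-2, 22Rv1 and PC3 carried a scramble shRNA or shCSN5, and in the inhibitor experiment the same lines had DMSO or CSN5i-3. The authors processed the reads with Partek Flow, whose version is not given. The aligner, the genome build and the strand counted are not given in the sources used here.

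The authors deposited 6 tables of counts per gene and library. Whole-number values, library totals in the range of sequencing depths and replicates that differed by more than counting error were checked in each table. LNCaP and PC3 share a table in the knockdown experiment, 22Rv1 and C4-2 share another, and each line has its own in the inhibitor experiment. Of the tables, 4 hold 57445 Ensembl identifiers, of which 89.6% matched a gene name of the reference. The table of the LNCaP inhibitor experiment holds 21549 symbols (96.0% matched), and that of C4-2 holds 16603 symbols (95.9% matched, 1 entry without a gene name). No gene in these 2 symbol tables had a maximum below 3 counts, so low genes had been left out before deposition. Symbols turned into dates were found in 3 tables. The 21 in the LNCaP inhibitor table were left as they were. The 28 in each of the tables of 22Rv1 were replaced through their Ensembl identifiers. Fits that joined a symbol table to another used symbols found once in each table, and a symbol with more than 1 Ensembl identifier was tested once per identifier, so a list can have 1 more measured entry than members.

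Groups follow titles and descriptions. Titles and descriptions of the C4-2 inhibitor experiment name opposite treatments for each pair, so this comparison is given only as titled C5i minus titled NT and was kept out of the fits across lines. A characteristic of PC3 shCSN5 replicate 2 names a drug-treated cell, and its title and description, both naming shCSN5, were used. Nothing in the labels says that replicates are separate cultures, so the p values measure only the spread between these libraries. Library totals ran from 20.6 to 50.9 M counts. Between the 2 libraries of a group the chi-square per gene ran from 1.72 in PC3 DMSO to 76.6 in LNCaP shCSN5, where counting error alone gives about 1.

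Each comparison was tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 on its own 4 libraries, with 2 residual degrees of freedom, TMM scaling, filterByExpr with a minimum count of 10 and Benjamini-Hochberg adjusted p under 0.05. The SE is the absolute log2 fold change divided by the square root of F. Average effects over lines had the line as a term. Differences between lines, and between knockdown and inhibitor within a line, were tested as interaction terms. A group with 3 or fewer counts in all was set to a floor of 3 counts over the group if it had none, which gives a lower bound, and otherwise its ratio is given with a 95% counting interval. Intervals and floors cover counting error only.

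Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with the correlation estimated from the libraries, in lists with at least 3 measured members, adjusted over the lists of a comparison. The estimated form rests on the residual degrees of freedom, 2 in each comparison, so it could hardly call any list there after adjustment. The 34 lists come from textbook knowledge: COP9 signalosome subunits, cullins and neddylation, cullin ligase substrate receptors, androgen receptor induced genes, luminal prostate markers, epithelial adhesion and keratins, basal prostate markers, mesenchymal genes high in PC3-type cells, neuroendocrine markers, fibroblast markers, leukocyte markers, p53 target genes, NRF2 target genes, G1/S and DNA replication, G2/M, CDK inhibitors and D-type cyclins, homologous recombination and Fanconi genes, ATF4 and integrated stress response, endoplasmic reticulum chaperones, heat shock genes, proteasome subunits, autophagy and lysosome, NF-kB target genes, interferon-stimulated genes, hypoxia genes, cholesterol synthesis, fatty acid synthesis, MYC and ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, apoptosis regulators, TGF-beta, SMAD and YAP targets, Wnt target genes and immediate early genes. Some genes sit in more than 1 list, 6 of the p53 target genes among them.

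The grouping, tests, lists, alternatives and naming rule were fixed before the data were examined. Genes named in a comparison are COPS5, the 5 largest increases and 5 largest decreases with a mean of at least 5 CPM and both libraries of one group above both of the other, passing over clone-based and uncharacterised names, and up to 2 higher and 2 lower members of each list with the smallest adjusted p. The fits over lines name the same 5 and 5. Other genes are said to be chosen after their values were seen. A few genes that the rule picks are not reported here.

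Alternatives were DESeq2 1.42.0, its size factors in edgeR, total counts in place of TMM, no low-count filter, calls of at least 2-fold, a block for replicate number, a spread shared by all libraries of an experiment, an estimated correlation for the lists, and leaving out each library in turn. With 1 library left in a group, the fit takes that library to vary like the other group. Total counts and the shared spread were applied to single comparisons. Tables were read with data.table (version 1.17.8) and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

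The tests were tested on simulated data with 200 changed genes at the spread of each comparison. Far more genes were called in the data, so the shares below need not hold there. Among the 8 comparisons 84.8% to 98.5% of 4-fold changes, 29.9% to 89.6% of 2-fold changes and 1.5% to 80.6% of 1.5-fold changes were called. False calls made up 24.3% of calls in 22Rv1 with CSN5i-3, 12.6% in LNCaP with shCSN5, 9.5% in PC3 with shCSN5, 9.3% in LNCaP with CSN5i-3 and 4.7% to 6.8% in the other comparisons, against an aim of 5%. They made up 5.3% and 4.8% for the average over lines in the knockdown and inhibitor experiments, 10.3% and 9.9% for the difference between lines, and 10.4%, 13.4% and 5.5% for knockdown against inhibitor in LNCaP, 22Rv1 and PC3. Camera called a list of 25 genes shifted 1.5-fold in each of the 8 comparisons and 0 of 30 unshifted lists in each. Simulated genes were drawn independently of each other, so this could not show false calls from correlated genes.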

Results

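RNA from 4 human prostate cancer cell lines was measured in 32 libraries, which form 16 groups of 2. LNCaP is an androgen-dependent line, C4-2 is a castration-resistant line derived from LNCaP, 22Rv1 is another castration-resistant line, and PC3 is an androgen-independent line without functional p53. The first experiment compared an shRNA against CSN5 (shCSN5) with a scramble shRNA in all 4 lines. CSN5, encoded by COPS5, is the catalytic subunit of the COP9 signalosome, which removes NEDD8 from cullin-RING ubiquitin ligases. The second experiment compared CSN5i-3, an inhibitor of CSN5, with DMSO, at 5 µM in LNCaP and 22Rv1 and at 10 µM in PC3. In C4-2 the labels of the second experiment conflict: the pair titled C5i is described as DMSO, and the pair titled NT is described as CSN5i-3 at 1 µM. PC3 shCSN5 replicate 2 carries a characteristic naming a drug-treated cell beside a title and a description naming shCSN5, which were used. Library totals ran from 20.6 to 32.5 M counts in the shRNA experiment and from 29.5 to 50.9 M counts in the inhibitor experiment. Changes below are log2 fold changes, treated minus control, each ± SE with n = 2 libraries per group, and levels are CPM, counts relative to the scaled library total. "Adjusted over the list alone" gives the members changed when only the list's own genes are corrected for. Within a comparison, camera with an estimated correlation had 2 residual degrees of freedom and could hardly call any list after adjustment. That it called none there therefore does not judge the calls with the preset correlation.

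COPS5, the gene targeted by the shRNA, was lower with shCSN5 in every library of every line. In LNCaP it stood at 53.4 and 52.7 CPM in the 2 scramble libraries and at 2.90 and 1.79 CPM in the 2 shCSN5 libraries, a change of -4.50 ± 0.26. In C4-2 the scramble libraries held 130.2 and 115 CPM and the shCSN5 libraries 10.5 and 10.4 CPM (-3.56 ± 0.12). In 22Rv1 it went from 99.7 and 115 CPM to 17.2 and 16.4 CPM (-2.68 ± 0.11), and in PC3 from 114 and 107 CPM to 11.8 and 12.6 CPM (-3.18 ± 0.12). The edgeR adjusted p values were 0.00021, 1.2e-05, 3.4e-08 and 0.0022. With CSN5i-3, COPS5 rose in PC3, where 77.1% of all genes tested were called, by 0.48 ± 0.033 (72.9 and 73.8 CPM to 102 and 102 CPM, adjusted p = 1.1e-19). In LNCaP it was at 49.99 and 46.0 CPM with DMSO and 49.0 and 54.5 CPM with the inhibitor (0.11 ± 0.087, adjusted p = 0.33; without DMSO replicate 1 it passed, at 0.17 and adjusted p = 0.029), and in 22Rv1 at 92.5 and 78.9 CPM against 91.5 and 100.4 CPM (0.16 ± 0.15, adjusted p = 0.48). Of the 10 measured COP9 signalosome subunits, COPS5 was the only member called with shCSN5 in C4-2 and in PC3.

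**Figure D1:**
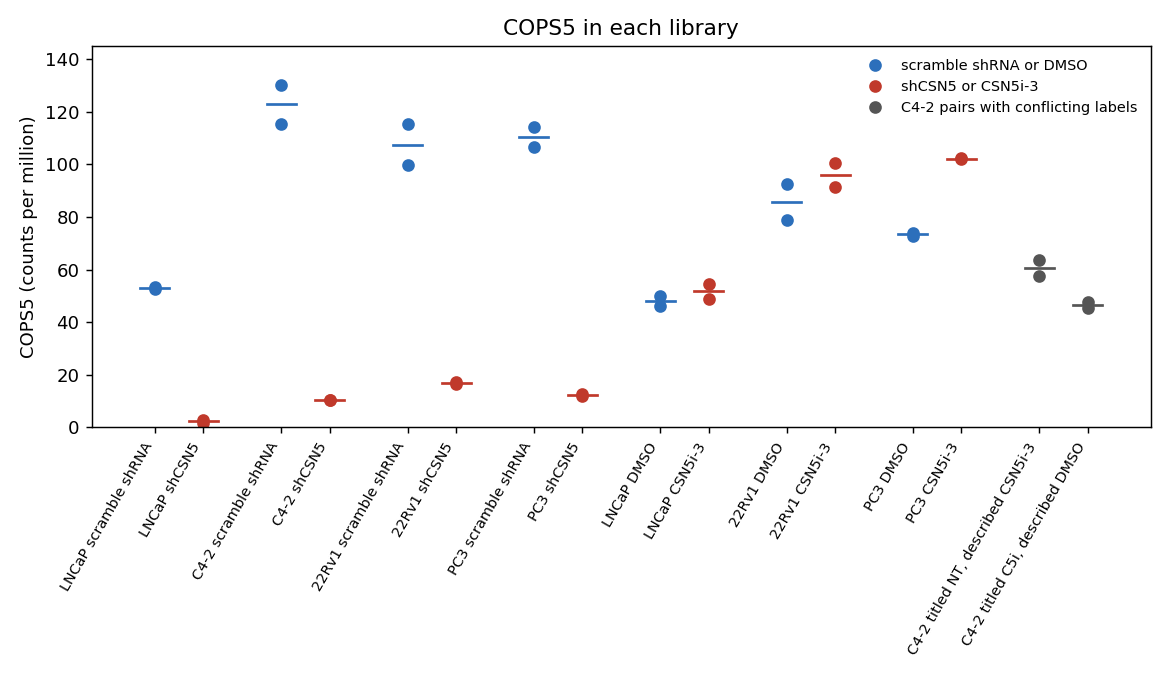
COPS5 in CPM, on a linear axis from 0, with 1 point per library and a bar at the mean of each group of 2, and the C4-2 inhibitor experiment pairs in grey. The shCSN5 libraries sit between 1.79 and 17.2 CPM, and the scramble libraries between 52.7 and 130.2 CPM.

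In LNCaP, genes of cell division fell with shCSN5. All 25 measured G2/M genes fell (25 adjusted over the list alone), with a median of -3.86, among them HMMR, a spindle-associated protein, at -5.05 ± 0.20 and TPX2, a spindle assembly factor, at -3.40 ± 0.16. Of 27 G1/S and DNA replication genes, 25 fell (25 adjusted over the list alone; median -2.70), including RRM2, the small subunit of ribonucleotide reductase, at -3.96 ± 0.20 and MCM7, part of the replicative helicase, at -2.70 ± 0.12. Of 14 homologous recombination and Fanconi genes, 13 fell (13 adjusted over the list alone; median -3.52), with RAD54L at -3.99 ± 0.17. The 5 largest decreases under the naming rule were BRCA2 (-5.76 ± 0.25), KIF14 (-5.48 ± 0.26), KNL1 (-5.43 ± 0.29), MYBL2 (-5.27 ± 0.21), a transcription factor of cell cycle genes, and CENPE (-5.24 ± 0.28). Of 24 p53 target genes, 20 rose and none fell (21 adjusted over the list alone; median 1.07): CDKN1A, which encodes the cell cycle inhibitor p21, rose by 2.59 ± 0.13, from 308 to 1850 CPM, and TP53I3 by 2.87 ± 0.17. Of 16 NF-kB target genes, 11 rose (14 adjusted over the list alone; median 1.19), among them IL32 at 2.01 ± 0.19 and BIRC3 at 1.60 ± 0.19. Of 13 genes of epithelial adhesion and keratins 6 rose (8 adjusted over the list alone), with OCLN, a tight junction protein, at 2.02 ± 0.17. Of 15 autophagy and lysosome genes 8 rose with 1 lower (11 adjusted over the list alone), with WIPI1 at 1.68 ± 0.18. The 5 largest increases were ADGRF1 (6.30 ± 0.36), the antisense transcript SSTR5-AS1 (6.16 ± 0.35, uncertain since the strand counted is not given), MMP12 (6.08 ± 0.34), EDN1 (5.90 ± 0.27) and FAM131B (5.72 ± 0.21). The androgen receptor induced genes went both ways, with 9 higher and 6 lower of 24 (16 adjusted over the list alone): STEAP4 was at 2.83 ± 0.24 and ZBTB10 at -1.77 ± 0.16, and the list's median of -0.03 and mean of 0.07 differ in sign. With camera the first 7 lists were called, at adjusted p from 2.14e-21 for G2/M to 0.0149 for autophagy and lysosome, and none was called with an estimated correlation (adjusted p = 0.206 to 0.401 with an estimated correlation). In edgeR 5326 of 14920 genes changed, 2733 higher and 2593 lower, and 2705 of them by at least 2-fold. The count was 2109 without scramble replicate 1, 2166 without scramble replicate 2, 10479 without shCSN5 replicate 1 and 11209 without shCSN5 replicate 2.

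In C4-2, all 24 measured p53 target genes rose with shCSN5 (24 adjusted over the list alone; median 1.29), CDKN1A by 2.67 ± 0.11 and TP53I3 by 2.94 ± 0.13. All 25 G2/M genes fell (25 adjusted over the list alone; median -1.65), among them CDC20, an activator of the anaphase-promoting complex, at -2.08 ± 0.12 and KIF20A at -1.91 ± 0.10. Of 27 G1/S and DNA replication genes, 26 fell (26 adjusted over the list alone; median -1.54), with RRM1 at -1.95 ± 0.11. Of 14 homologous recombination and Fanconi genes 13 fell (13 adjusted over the list alone; median -1.62), with BRCA1 at -1.64 ± 0.11. Of 20 genes of the ATF4 and integrated stress response, 13 rose and none fell (13 adjusted over the list alone; median 0.63): DDIT4, an inhibitor of mTORC1 signalling, rose by 1.96 ± 0.10 and SESN2 by 1.80 ± 0.15. Of 24 androgen receptor induced genes, 12 fell and 3 rose (17 adjusted over the list alone; median -0.33), FKBP5 at -1.44 ± 0.10 and NCAPD3 at -1.49 ± 0.098 against TMPRSS2 at 0.94 ± 0.086. Of 19 apoptosis regulators, 12 rose and 2 fell (14 adjusted over the list alone), with BIRC3 at 2.80 ± 0.20 and BIRC5, which encodes survivin, at -1.80 ± 0.11. Of 19 MYC and ribosome biogenesis genes 10 fell (11 adjusted over the list alone; median -0.35), with NOP56 at -0.70 ± 0.087. Among the 5 largest increases were CAMK2N1 (5.24 ± 0.12), TNFSF15 (5.23 ± 0.12), GDF15, a stress-induced cytokine (4.52 ± 0.23), and CA1 (4.02 ± 0.20). The largest decreases after COPS5 were TTN (-3.14 ± 0.18), RND3 (-2.99 ± 0.17), TMEM100 (-2.89 ± 0.18) and CCDC141 (-2.80 ± 0.16). Camera called these 8 lists at adjusted p from 1.89e-21 for G2/M to 0.00853 for apoptosis regulators, and none with an estimated correlation (adjusted p = 0.294 for each). In edgeR 4754 of 14874 genes changed, 2338 higher and 2416 lower. Of these, 1662 changed by at least 2-fold. The count was 3139 with no low-count filter, 3023 without shCSN5 replicate 1 and 3036 without shCSN5 replicate 2.

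In 22Rv1, all 16 measured immediate early genes rose with shCSN5 (16 adjusted over the list alone; median 1.75), among them ATF3, a stress-induced transcription factor, at 2.43 ± 0.08 and DUSP6, a phosphatase that limits ERK signalling, at 2.74 ± 0.10. All 6 measured basal prostate markers rose (6 adjusted over the list alone; median 3.37), with KRT15, a basal keratin, at 4.47 ± 0.21. Of 12 mesenchymal genes high in PC3-type cells 7 rose with 2 lower (9 adjusted over the list alone; median 0.99), with ANXA1 at 3.33 ± 0.13. All 25 G2/M genes fell (25 adjusted over the list alone; median -1.27), TOP2A at -1.86 ± 0.083. Of 28 G1/S and DNA replication genes 27 fell with 1 higher (28 adjusted over the list alone; median -1.15), PCNA, the sliding clamp of DNA polymerases, at -1.72 ± 0.079. All 14 homologous recombination and Fanconi genes fell (14 adjusted over the list alone; median -1.07), BRCA1 at -1.50 ± 0.08. Of 24 p53 target genes, 20 rose and 1 fell (21 adjusted over the list alone; median 0.77), with PHLDA3 at 2.32 ± 0.17, CDKN1A at 1.04 ± 0.084 and TP53INP1 at -0.81 ± 0.084. Of 23 androgen receptor induced genes, 15 fell and 4 rose (19 adjusted over the list alone; median -0.32), and KLK3, which encodes PSA, was among those that rose, by 2.20 ± 0.079. Of 15 autophagy and lysosome genes, 11 rose (13 adjusted over the list alone), with GABARAPL1 at 1.43 ± 0.088. Of 20 cholesterol synthesis genes 13 rose and 2 fell (16 adjusted over the list alone). The 5 largest increases were HR (5.98 ± 0.26), the collagenase MMP1 (5.90 ± 0.22), TCIM (4.99 ± 0.12), BNIPL (4.62 ± 0.23) and ITM2A (4.60 ± 0.22). The largest decreases beside COPS5 were IGF1 (-3.23 ± 0.19), CHRNA2 (-3.07 ± 0.17), ADRA2A (-2.56 ± 0.20) and MYBL1 (-2.50 ± 0.16). CXCL8, counted 3 times in the scramble libraries, was 28.2-fold higher (95% counting interval 9.35 to 140), and OASL, counted 2 times, 17.6-fold higher (4.54 to 151). Camera called these 10 lists at adjusted p from 4.83e-20 for G2/M to 0.00798 for the mesenchymal genes, and none with an estimated correlation (adjusted p = 0.28 for each). In edgeR 6988 of 15919 genes changed, 3595 higher and 3393 lower. Of these, 1914 changed by at least 2-fold. Total counts gave 4279 higher and 2949 lower, and DESeq2 2536 higher and 2747 lower. Without shCSN5 replicate 1 the edgeR count with TMM was 4206.

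In PC3, genes of the ATF4 and integrated stress response rose with shCSN5: 17 of 20 rose and none fell (18 adjusted over the list alone; median 1.61), among them ATF3 at 3.26 ± 0.14 and ASNS, asparagine synthetase, at 2.03 ± 0.12. Of 22 NF-kB target genes, 16 rose and none fell (20 adjusted over the list alone; median 1.49), with CXCL8, a neutrophil chemokine, at 2.89 ± 0.13, from 15.2 to 114 CPM, and BIRC3 at 2.57 ± 0.15. Of 21 interferon-stimulated genes 6 rose (12 adjusted over the list alone; median 0.52), IFIT2 by 1.86 ± 0.11 and OAS1 by 1.05 ± 0.14. Of 12 heat shock genes, 10 fell and 1 rose (11 adjusted over the list alone; median -0.94): HSPA8, the constitutive HSP70, fell by 1.24 ± 0.10 and DNAJA1 by 1.03 ± 0.11. Of 19 hypoxia genes, 9 fell and 1 rose (14 adjusted over the list alone; median -0.72), with BNIP3 at -1.57 ± 0.10 and the glycolytic enzyme PGK1 at -1.34 ± 0.092 against VEGFA at 0.88 ± 0.12. Of 31 proteasome subunits 17 fell and none rose (30 adjusted over the list alone; median -0.50), with PSMC5 at -0.69 ± 0.092 (adjusted p = 0.013, 0.068 without shCSN5 replicate 1 and 0.051 without shCSN5 replicate 2). Of 23 oxidative phosphorylation genes 10 fell (13 adjusted over the list alone; median -0.38). Of 27 G1/S and DNA replication genes 16 fell (24 adjusted over the list alone; median -0.67), PCNA by 1.28 ± 0.087. Of 25 G2/M genes 16 fell (19 adjusted over the list alone; median -0.50), KIF20A by 0.92 ± 0.089. Of 23 p53 target genes, 3 rose and 1 fell (6 adjusted over the list alone; camera adjusted p = 0.707). Of 14 homologous recombination and Fanconi genes 1 rose and 2 fell (3 adjusted over the list alone; camera adjusted p = 0.643), with a median of 0, a mean of -0.02 and a test pointing down. The 5 largest increases were OSTN (5.06 ± 0.34), S100P (4.23 ± 0.20), CHAC1, an enzyme that degrades glutathione (3.68 ± 0.28), PI3 (3.53 ± 0.10) and GDF15 (3.53 ± 0.29). The largest decreases after COPS5 were GABBR2 (-2.11 ± 0.16), COL6A3 (-1.83 ± 0.12), B4GALNT1 (-1.74 ± 0.17) and UNG (-1.63 ± 0.098). Camera called the first 9 lists at adjusted p from 3.55e-13 to 8.08e-05, and none with an estimated correlation (adjusted p = 0.207 to 0.434). In edgeR 2578 of 15465 genes changed, 1586 higher and 992 lower. Of these, 917 changed by at least 2-fold. DESeq2 gave 1105 higher and 1163 lower, and edgeR with total counts, which moved the median of all genes from 0.04 to 0.11, gave 1969 higher and 702 lower. The count was 4273 with no low-count filter, 4522 with the spread shared by all shRNA libraries, 4750 without scramble replicate 1, 4160 without scramble replicate 2, 868 without shCSN5 replicate 1 and 1070 without shCSN5 replicate 2.

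Over the 4 lines together, with the line as a term of the model, 6359 of 18601 genes changed with shCSN5 in edgeR, 3630 higher and 2729 lower. GDF15 rose by 4.24 ± 0.21 on average, and its change did not pass the test of a difference between lines (adjusted p = 0.32). TCIM (4.60 ± 0.30), TNFSF15 (3.85 ± 0.44), MMP1 (3.23 ± 0.71) and the receptor phosphatase PTPRH (2.83 ± 0.44) rose on average, and COPS5 (-3.42 ± 0.20), DHRS2 (-2.84 ± 0.34), MYBL2 (-2.35 ± 0.44), the nuclear lamin LMNB1 (-2.19 ± 0.23) and ORC1, of the origin recognition complex (-2.09 ± 0.29), fell, each with a change that differed between lines (adjusted p from 3.1e-08 to 0.00091). The test of a difference between lines was passed by 7221 genes. Members counted as above or below, here and in later paragraphs, are those whose own difference passed. G2/M genes fell less in C4-2 than in LNCaP, by a median difference of 2.00 with 25 of 25 members above (camera adjusted p = 1.05e-33, and adjusted p = 0.0123 with an estimated correlation), and less in PC3 than in LNCaP, by 3.16 (camera adjusted p = 3.64e-29, and 0.0146 as the adjusted p with an estimated correlation). The ATF4 list was higher in PC3 than in LNCaP by 1.90 with 18 of 20 members above (adjusted p = 0.00321 with an estimated correlation), and p53 target genes were lower in PC3 than in C4-2 by a median of -1.22 with 18 of 24 members below (adjusted p = 0.00451 with an estimated correlation). Basal prostate markers were higher in 22Rv1 than in C4-2 by 2.34 (adjusted p = 0.00614 with an estimated correlation), and immediate early genes by 1.29 (adjusted p = 0.00277 with an estimated correlation). LNCaP and PC3 shared a count table and 22Rv1 and C4-2 another, so a difference between lines of separate tables may also hold a difference between sequencing projects. Genes called in the same direction in all 4 lines numbered 158 higher and 227 lower of 12531 tested in each, where independent calls would give 6.41 and 5.44.

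In LNCaP, 25 of 25 G2/M genes fell with CSN5i-3 at 5 µM (25 adjusted over the list alone; median -5.23), with BIRC5 at -5.82 ± 0.099, from 94.0 to 1.66 CPM, and CDC20 at -5.92 ± 0.11. Of 27 G1/S and DNA replication genes 26 fell (27 adjusted over the list alone; median -2.53), RRM2 by 5.55 ± 0.10. Of 14 homologous recombination and Fanconi genes 13 fell (13 adjusted over the list alone; median -3.24), RAD54L at -4.61 ± 0.13. All 14 luminal prostate markers fell (14 adjusted over the list alone; median -1.13) and 19 of 23 androgen receptor induced genes fell with 1 higher (20 adjusted over the list alone; median -0.99): KLK3 fell by 2.86 ± 0.053, from 2560 to 352 CPM, and ELL2, an elongation factor, rose by 0.53 ± 0.09. Of 24 p53 target genes 23 rose (24 adjusted over the list alone; median 1.43), with CDKN1A at 3.52 ± 0.065. Of 22 NRF2 target genes 21 rose (22 adjusted over the list alone; median 1.34), with TXNRD1, thioredoxin reductase, at 2.24 ± 0.063 and FTH1, the ferritin heavy chain, at 2.06 ± 0.048. Of 13 TGF-beta, SMAD and YAP targets, 11 rose and 1 fell (12 adjusted over the list alone; median 1.91), ID2 by 3.08 ± 0.082 and CCN1 by 2.86 ± 0.085. Of 15 NF-kB target genes 12 rose and 1 fell (13 adjusted over the list alone; median 1.49), IL32 by 4.22 ± 0.092. Of 12 fatty acid synthesis genes, 10 fell and 2 rose (12 adjusted over the list alone; median -0.83), with the desaturase FADS2 at -1.65 ± 0.059. Of 8 leukocyte markers only 3 were measured, and all 3 rose (3 adjusted over the list alone). Their median was 6.26 as fitted, and 4.26 with 2 members of 3 or fewer DMSO counts set to the floor of 3 counts. Those 2 members passed the low-count filter only through the CSN5i-3 libraries, so their direction, and in part the list's call, followed from the filter. CD68 was at 24.8 CPM against 0.319 CPM with DMSO. ITGAM, counted 3 times with DMSO, was 19.2-fold higher (95% counting interval 6.24 to 95.8). The 5 largest increases were TCIM (6.87 ± 0.12), EDN1 (6.62 ± 0.20), KRT75 (6.61 ± 0.18), CD68 (6.26 ± 0.15) and NEURL3 (6.01 ± 0.23). The 5 largest decreases were KIF20A (-7.41 ± 0.17), DLGAP5 (-7.02 ± 0.15), TOP2A (-6.15 ± 0.15), KIF4A (-6.13 ± 0.16) and FAM83D (-6.12 ± 0.14). Camera called these 11 lists at adjusted p from 1.31e-19 for G2/M to 0.0192 for the leukocyte markers, and none with an estimated correlation (adjusted p = 0.134 to 0.255). In edgeR 9598 of 18238 genes changed, 4772 higher and 4826 lower. Of these, 3443 changed by at least 2-fold. With total counts, which moved the median of all genes to -0.10, 3893 were higher and 5886 lower. The edgeR count with TMM was 6242 without CSN5i-3 replicate 1 and 6262 without CSN5i-3 replicate 2.

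In 22Rv1, CSN5i-3 at 5 µM lowered 27 of 28 G1/S and DNA replication genes (27 adjusted over the list alone; median -2.06), with the origin factors GINS2 at -2.46 ± 0.16 and MCM10 at -2.48 ± 0.17. All 25 G2/M genes fell (25 adjusted over the list alone; median -1.69), MKI67, the proliferation marker Ki-67, by 2.05 ± 0.14. All 14 homologous recombination and Fanconi genes fell (14 adjusted over the list alone; median -2.00), BRCA1 by 2.26 ± 0.15. Of 15 endoplasmic reticulum chaperones 10 fell and none rose (11 adjusted over the list alone; median -0.80), PDIA4, a disulfide isomerase, by 1.59 ± 0.14 and MANF by 1.54 ± 0.15. Of 9 neuroendocrine markers 5 fell (5 adjusted over the list alone; median -0.97), with SRRM4, a splicing factor of neural exons, at -2.44 ± 0.14 and ENO2 at -1.27 ± 0.16. Of 6 basal prostate markers 5 rose (6 adjusted over the list alone; median 3.24), KRT15 by 3.98 ± 0.26. Of 13 mesenchymal genes high in PC3-type cells 8 rose with 1 lower (11 adjusted over the list alone; median 2.16), MET by 2.87 ± 0.18. Of 16 immediate early genes 11 rose (12 adjusted over the list alone; median 1.11), with DUSP5 at 5.47 ± 0.23. Of 14 TGF-beta, SMAD and YAP targets 9 rose with 1 lower (10 adjusted over the list alone; median 1.0), with CCN2 at 3.55 ± 0.20. Of 24 p53 target genes 17 rose (19 adjusted over the list alone; median 1.24), with CDKN1A at 3.11 ± 0.18 and GDF15 at 5.11 ± 0.47. Of 19 hypoxia genes 6 rose and 1 fell (7 adjusted over the list alone; median 0.30), with ADM at 2.62 ± 0.23. CXCL8, counted 3 times with DMSO, was 46.2-fold higher (95% counting interval 15.5 to 227), and PTPRC, a leukocyte marker counted 3 times with DMSO, 24.3-fold higher (7.98 to 120). The 5 largest increases were FXYD4 (6.28 ± 0.37), ANXA3 (6.12 ± 0.23), the YAP target ANKRD1 (6.01 ± 0.30), PRSS3 (5.74 ± 0.28) and MMP1 (5.69 ± 0.30). The 5 largest decreases were IGF1 (-3.78 ± 0.23), DMC1 (-3.56 ± 0.21), DERL3 (-3.55 ± 0.33), CLSTN2 (-3.53 ± 0.22) and CHRNA2 (-3.49 ± 0.30). Camera called these 11 lists at adjusted p from 1.61e-19 for G1/S to 0.0148 for hypoxia, and none with an estimated correlation (adjusted p = 0.241 for each). In edgeR 4010 of 16739 genes changed, 1970 higher and 2040 lower. Of these, 2559 changed by at least 2-fold. The count was 6526 with the spread shared by all inhibitor libraries, in a fit limited to symbols found once in all 4 tables.

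In PC3, CSN5i-3 at 10 µM raised all 22 measured interferon-stimulated genes (22 adjusted over the list alone; median 2.50), among them MX1, an antiviral GTPase, at 2.52 ± 0.025, from 162 to 926 CPM, and OAS1, an oligoadenylate synthetase, at 2.56 ± 0.027. RSAD2 (4.94 ± 0.044), XAF1 (4.46 ± 0.16), TRIM22 (3.61 ± 0.11) and IFITM1 (3.23 ± 0.031), all known interferon-induced genes, were 4 of the 5 largest increases, with ATP6V0D2 at 4.98 ± 0.16. Of 15 endoplasmic reticulum chaperones 14 rose and 1 fell (15 adjusted over the list alone; median 0.77), with HSPA5, which encodes BiP, at 1.51 ± 0.022 and DNAJB9 at 2.31 ± 0.037. Of 20 cholesterol synthesis genes 16 rose and 3 fell (19 adjusted over the list alone; median 0.72), with INSIG1 at 2.13 ± 0.053. Of 15 autophagy and lysosome genes 11 rose and 3 fell (14 adjusted over the list alone), WIPI1 by 1.82 ± 0.03. All 25 G2/M genes fell (25 adjusted over the list alone; median -2.03), BIRC5 by 3.48 ± 0.037. Of 27 G1/S and DNA replication genes 26 fell with 1 higher (27 adjusted over the list alone; median -0.99), RRM2 at -3.19 ± 0.048. Of 14 homologous recombination and Fanconi genes 13 fell (13 adjusted over the list alone; median -1.81), FANCD2 by 2.25 ± 0.076. Of 31 proteasome subunits 27 fell and 2 rose (29 adjusted over the list alone; median -0.48), PSMD2 by 1.11 ± 0.023. Of 23 oxidative phosphorylation genes 20 fell (20 adjusted over the list alone; median -0.52), SDHA, of succinate dehydrogenase, by 0.95 ± 0.03. Of 14 TGF-beta, SMAD and YAP targets 10 fell and 4 rose (14 adjusted over the list alone; median -0.80), with ID1 at -2.67 ± 0.047 and SMAD7 at 1.78 ± 0.11. The NF-kB target genes went both ways, with 8 higher and 14 lower of 23 (22 adjusted over the list alone; camera adjusted p = 0.406): IL1B fell by 4.34 ± 0.044 and CXCL1 by 2.61 ± 0.029, and CXCL8 rose by 1.0 ± 0.022. Of 5 fibroblast markers 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0717), COL1A1 by 1.96 ± 0.052. The largest decreases were CSF3 (-5.86 ± 0.077), TNS4 (-5.08 ± 0.18), MUC5AC (-4.52 ± 0.14) and the antisense transcript SSTR5-AS1 (-4.47 ± 0.12, uncertain for want of the strand), with IL1B. Camera called the first 10 of these lists but not the NF-kB and fibroblast lists, at adjusted p from 4.33e-16 for the interferon-stimulated genes to 0.0368 for the TGF-beta list, and none with an estimated correlation (adjusted p = 0.208 to 0.381). In edgeR 12659 of 16423 genes changed, 6328 higher and 6331 lower. Of these, 3588 changed by at least 2-fold. The count was 7885 with the spread shared by all inhibitor libraries, in a fit limited to symbols found once in all 4 tables.

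Over LNCaP, 22Rv1 and PC3 together, 5774 of 19006 genes changed with CSN5i-3 in edgeR, 2915 higher and 2859 lower. The largest average increases were ADGRF4 (3.97 ± 0.63), MMP1 (3.90 ± 0.50), DUSP5 (3.88 ± 0.73), MMP10 (3.45 ± 0.35) and LURAP1L (3.14 ± 0.57). The largest decreases were BIRC5 (-3.62 ± 0.53), TOP2A (-3.62 ± 0.60), SPC25, a kinetochore protein (-3.56 ± 0.50), SHCBP1 (-3.48 ± 0.45) and FAM83D (-3.40 ± 0.58). Each of these 10 changes differed between lines (adjusted p from 1.2e-08 to 0.0043). The test of a difference between lines was passed by 8671 genes. Interferon-stimulated genes were higher in PC3 than in LNCaP by a median of 2.00 with 15 of 19 members above (camera adjusted p = 3.34e-07, and adjusted p = 0.00907 with an estimated correlation), and higher than in 22Rv1 by 1.65 with 11 of 19 above (adjusted p = 0.0126 with an estimated correlation). NRF2 target genes were lower in PC3 than in LNCaP by a median of -1.56 with 18 of 24 below (adjusted p = 0.00413 with an estimated correlation), as were p53 target genes by -1.26 (adjusted p = 0.00413 with an estimated correlation). Luminal prostate markers were less reduced in 22Rv1 than in LNCaP, by a median of 1.22 with 9 of 14 above (adjusted p = 0.0444 with an estimated correlation), and G2/M genes less reduced by 3.54 with 24 of 25 above (adjusted p = 0.0387 with an estimated correlation). Each line has its own table here and PC3 its own dose, so line, dose and sequencing project cannot be separated. Genes called in the same direction in all 3 lines numbered 523 higher and 803 lower of 13470, where independent calls would give 167 and 170.

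The C4-2 pair titled C5i differed from the pair titled NT in 11214 of 14966 genes in edgeR, 5535 higher and 5679 lower in the pair titled C5i, 5228 of them by at least 2-fold. With total counts, which moved the median of all genes to -0.21, 4493 were higher and 6806 lower. Which pair had the inhibitor is not settled by the labels, so every value here is titled C5i minus titled NT. All 25 G2/M genes were lower (25 adjusted over the list alone), with BIRC5 at -6.79 ± 0.12 and MKI67 at -5.71 ± 0.11, and their median was -5.46 as fitted. All 27 G1/S and DNA replication genes were lower (27 adjusted over the list alone; median -3.92), RRM2 at -8.10 ± 0.13, from 329 to 1.19 CPM. All 14 homologous recombination and Fanconi genes were lower (14 adjusted over the list alone; median -4.35), RAD54L at -5.68 ± 0.14. All 24 p53 target genes were higher (24 adjusted over the list alone; median 2.23), CDKN1A at 3.97 ± 0.07. All 20 genes of the ATF4 and integrated stress response were higher (20 adjusted over the list alone; median 1.99), ATF3 at 5.21 ± 0.078 and DDIT3, which encodes CHOP, at 3.5 ± 0.083. All 40 cytosolic ribosomal protein genes were higher (40 adjusted over the list alone; median 0.88), RPS19 at 1.34 ± 0.067. Of 14 luminal prostate markers 12 were lower and 1 higher (13 adjusted over the list alone; median -1.71), KLK3 at -2.84 ± 0.06 against TMPRSS2 at 0.87 ± 0.066. Of 21 NRF2 target genes 16 were higher and 3 lower (19 adjusted over the list alone; median 0.75), TXNRD1 at 2.89 ± 0.076. Of 19 apoptosis regulators 13 were higher and 4 lower (17 adjusted over the list alone; median 0.72), with BBC3, which encodes PUMA, at 4.33 ± 0.17 and PMAIP1, which encodes NOXA, at 3.15 ± 0.12. CPA4 was at 0 counts in the pair titled NT and at least 349-fold higher in the pair titled C5i, KRT75 was 495-fold higher (95% counting interval 137 to 4090) and NKX1-2 449-fold higher (124 to 3710), and CKAP2L was 439-fold lower (121 to 3630). TCIM (8.83 ± 0.18) and TRAF1 (7.12 ± 0.21) were the other large increases, and SHCBP1 (-8.90 ± 0.18), SPC25 (-8.52 ± 0.31), MCM10 (-8.47 ± 0.18) and HMMR (-8.27 ± 0.22) the other large decreases. COPS5 was at 57.4 and 63.6 CPM in the pair titled NT and at 47.5 and 45.5 CPM in the pair titled C5i (-0.38 ± 0.09, adjusted p = 0.0025, and 0.055 without the library titled C5i, replicate 2). Camera called these 9 lists at adjusted p from 3.36e-14 for G1/S to 0.0168 for apoptosis regulators, and none with an estimated correlation (adjusted p = 0.203 to 0.294).

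Within LNCaP, the changes with shCSN5 and with CSN5i-3 differed in 3826 of 17932 genes, 1240 above and 2586 below with the inhibitor. Luminal prostate markers were lower with the inhibitor than with the knockdown by a median of -1.57, with 11 of 14 below (camera adjusted p = 1.14e-09, and adjusted p = 0.203 with an estimated correlation), and NRF2 target genes higher by 0.95, with 12 of 22 above (camera adjusted p = 5.8e-08, and adjusted p = 0.203 with an estimated correlation). The LNCaP count was 2119 without scramble replicate 1, 1490 without scramble replicate 2, 7931 without shCSN5 replicate 2, 1820 without DMSO replicate 1, 2304 without DMSO replicate 2, 1491 without CSN5i-3 replicate 1 and 1589 without CSN5i-3 replicate 2. In 22Rv1 730 of 17039 genes differed, 406 above and 324 below: G1/S and DNA replication genes were lower with the inhibitor by a median of -0.95, with 18 of 28 below (adjusted p = 0.0309 with an estimated correlation), and endoplasmic reticulum chaperones by -0.88, with 9 of 15 below (camera adjusted p = 1.26e-10, and adjusted p = 0.0825 with an estimated correlation). The 22Rv1 count was 2028 with no low-count filter, 89 without scramble replicate 1, 69 without scramble replicate 2, 43 without shCSN5 replicate 1, 54 without shCSN5 replicate 2, 301 without DMSO replicate 1, 274 without DMSO replicate 2 and 1494 without CSN5i-3 replicate 1. In PC3 6559 of 16794 genes differed, 3442 above and 3117 below. The count was 4352 without CSN5i-3 replicate 1. Interferon-stimulated genes were higher with the inhibitor in PC3 by a median of 1.64, with 17 of 22 above (camera adjusted p = 6.51e-12, and adjusted p = 0.0368 with an estimated correlation), and NF-kB target genes lower by a median of -1.89, with 16 of 23 below (camera adjusted p = 2.37e-09, and adjusted p = 0.0368 with an estimated correlation). The ATF4 list was lower with the inhibitor in PC3 by a median of -1.53, with 18 of 20 below (camera adjusted p = 1.09e-07, and adjusted p = 0.107 with an estimated correlation). The experiments were sequenced under separate projects with their own controls, so each of these differences also spans projects. Across genes, which are not independent replicates, the correlation of the log2 fold changes of knockdown and inhibitor was 0.68 in LNCaP, 0.75 in 22Rv1 and 0.28 in PC3, and the C4-2 knockdown and the C4-2 pairs as titled gave 0.58. Genes called in the same direction in the 7 comparisons of shCSN5 in 4 lines and CSN5i-3 in 3 lines numbered 86 higher and 144 lower of 12313, where independent calls would give 0.0768 and 0.0725. Among the 86 were GDF15, PTPRH, DUSP5 and the epithelial transcription factor ELF3, chosen after their values were seen.

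**Figure D2:**
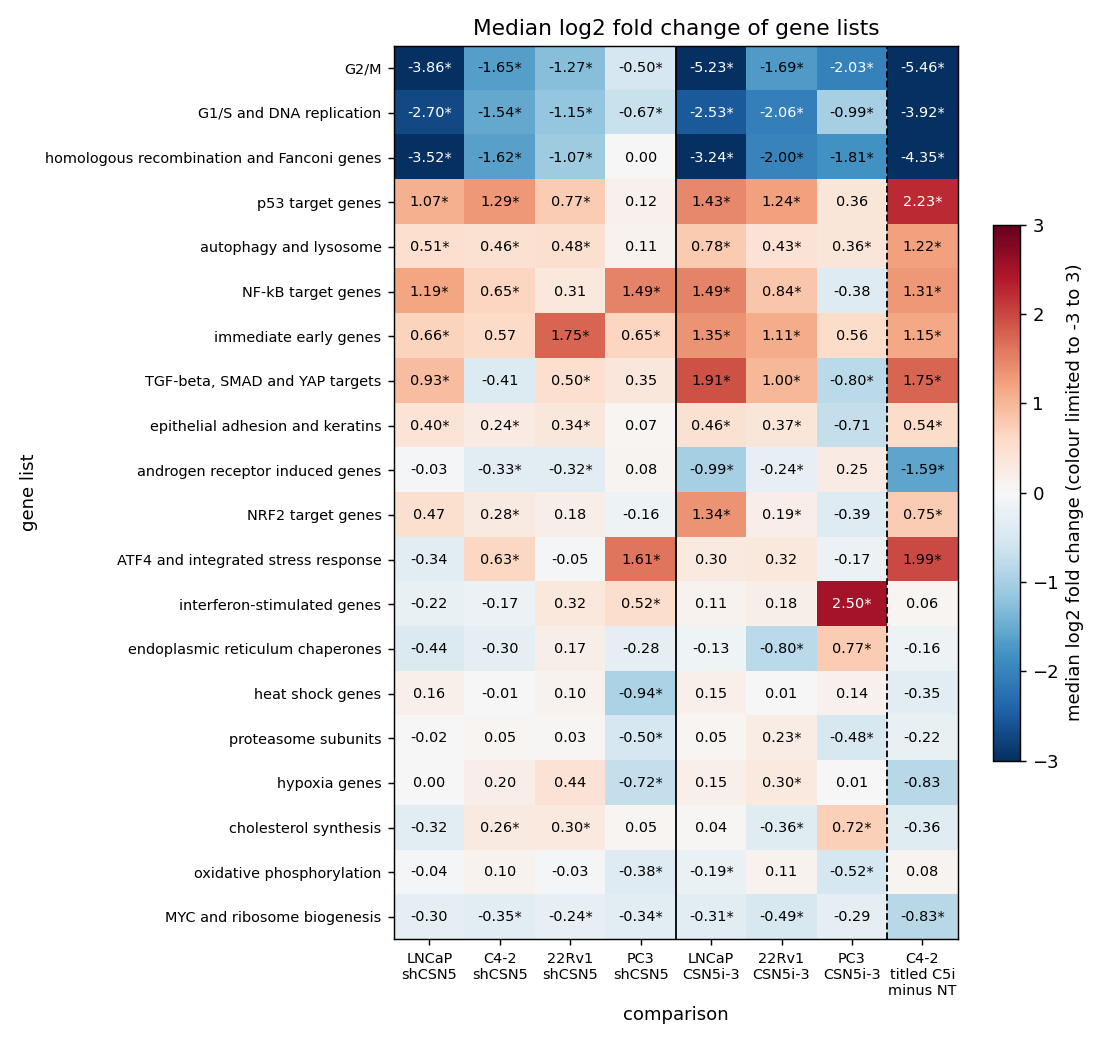
Heat map of the median log2 fold change of 20 of the gene lists in the 8 comparisons, with colour limited to -3 to 3, an asterisk where camera called the list, and the C4-2 pairs as titled C5i minus titled NT. The G2/M list lies below 0 in all 8, from -5.46 in the C4-2 pairs to -0.50 in PC3 with shCSN5, and the interferon-stimulated list reaches 2.50 in PC3 with CSN5i-3.

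Several lists were called in no comparison or in few. The COP9 signalosome subunits were called nowhere (camera adjusted p from 0.127 to 1), with 5 of 10 higher and 4 lower in PC3 with CSN5i-3 (9 adjusted over the list alone), COPS6 at -1.08 ± 0.028. The 26 cullins and neddylation genes were not called either (0.148 to 0.992 as the camera adjusted p): 7 rose and 13 fell in PC3 with CSN5i-3 (20 adjusted over the list alone), CUL7 by 1.16 ± 0.041. Of the cullin ligase substrate receptors, 13 rose and 10 fell in PC3 with CSN5i-3 (23 adjusted over the list alone; camera adjusted p = 0.48), and DTL, the receptor that targets CDT1, was at -3.81 ± 0.23 with shCSN5 and -4.64 ± 0.15 with CSN5i-3 in LNCaP. Beside these member counts in PC3 with CSN5i-3, 77.1% of all genes tested were called there. The list of CDK inhibitors and D-type cyclins was called nowhere (camera adjusted p from 0.542 to 1), although CDKN2C fell by 1.78 ± 0.16 and CDKN2B rose by 2.96 ± 0.21 in LNCaP with shCSN5, where 3 rose and 1 fell (7 adjusted over the list alone). The Wnt target genes were called nowhere (camera adjusted p from 0.0999 to 0.861), with DKK1, a secreted Wnt inhibitor, at 2.29 ± 0.083 in 22Rv1 with shCSN5, where 4 rose and 3 fell of 8 (7 adjusted over the list alone).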

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

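The tests of other splits of the libraries and of depth were set before the results were seen, and the tests of the C4-2 labels, the PC3 spread, scaling, the PC3 knockdown and dose were chosen only after the result was seen.

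The CSN5i-3 changes differed between lines in 8671 genes and the shCSN5 changes in 7221, each by an interaction test. Other splits of the libraries were tested for the average effects over lines only, not for these differences between lines. Of 100 splits of the shRNA libraries 1, the real one, gave as many genes (6359, the highest other 3919). Of 100 splits of the inhibitor libraries 1, the real one, did (5774, the highest other 1693). Treated and control libraries thus differed by more than regrouped libraries did. The labels do not say that replicates are separate cultures, so the splits cannot judge chance differences between cultures. The knockdown and inhibitor changes differed in 3826 genes in LNCaP, 730 in 22Rv1 and 6559 in PC3, where the experiment is confounded with its sequencing project.

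In C4-2 the conflict of titles and descriptions leaves open which pair had CSN5i-3. Read as titled, the G2/M median was -5.46, below 0 as in the 3 other lines with the inhibitor, and the lowest correlation across genes with those lines was 0.33, which is consistent with descriptions that were exchanged between the pairs. Read as described, the G2/M median would be 5.46, opposite to the other lines. The C4-2 knockdown argues against an opposite response to loss of CSN5 itself: with shCSN5 the G2/M median was -1.65, and the correlation across genes with titled C5i minus titled NT was 0.58. A response of C4-2 to the compound opposite to the other lines was not tested directly, since no other C4-2 library had the compound. Levels in the C4-2 scramble shRNA libraries argue against it for MYBL2, LMNB1, SKP2 and KLK3, chosen after their values were seen. With scramble shRNA they stood at 157, 253, 56.1 and 3620 CPM. They stood at 524, 247, 55 and 2510 CPM in the pair titled NT, and at 3.9, 9.04, 10.1 and 350 CPM in the pair titled C5i. These levels span sequencing projects, and CDT1, MYC and TMPRSS2, among others, lay nearer the control in the pair titled C5i.

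PC3 with CSN5i-3 gave 12659 genes in edgeR, against 9598 in LNCaP and 11214 between the C4-2 pairs. It did not keep the first place under every alternative: the C4-2 pairs gave 9806 against 7885 in PC3 with a shared spread, and 5228 against 3588 at 2-fold or more. Thinned to the lowest library total of the inhibitor experiment, 29.5 M counts, PC3 still gave 11808 genes, more than LNCaP, so greater depth is not the whole cause. With a spread shared by the inhibitor libraries the PC3 count was 1.07 times the LNCaP count, against 1.32 without sharing. That fit held only symbols found once in all 4 tables, so the gene set changed too. The limit set for the test, 1.5, could not decide on a small spread between the PC3 libraries, since both ratios lie within it. As a biological coefficient of variation, the spread between replicates was 0.0184 in PC3. It was 0.0815 in LNCaP, 0.182 in 22Rv1 and 0.0735 in the C4-2 pairs. PC3 thus had the smallest spread, but its part in the count was not separated.

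Interferon-stimulated genes rose in PC3 with CSN5i-3 and went both ways in the other lines, with 7 higher and 3 lower of 19 in LNCaP (median 0.11, camera adjusted p = 0.641) and 3 higher and 2 lower of 15 in 22Rv1 (median 0.18, camera adjusted p = 0.586). Scaling between libraries is argued against: a scaling factor moves all genes alike, and the list median lay 2.51 above the median of all genes, which was -0.01. A response of PC3 to loss of CSN5 by any means stays open, since the list median was 0.52 with shCSN5 in PC3 but did not differ from 22Rv1 with shCSN5 by a called amount (camera adjusted p = 0.345). The higher dose in PC3 cannot be told apart from the line, since PC3 had 1 dose.

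The other differences are lists called by camera in opposite directions, with the difference itself called. None of the opposite calls within a single comparison held with an estimated correlation (adjusted p from 0.196 to 0.403). Those tests had 2 residual degrees of freedom and could hardly pass after adjustment. The differences below come from fits with more libraries, so their adjusted p values cannot be set against these. TGF-beta, SMAD and YAP targets were lower with CSN5i-3 in PC3 than in LNCaP by a median difference of -2.95 (11 of 14 members below, adjusted p = 0.0338 with an estimated correlation) and than in 22Rv1 by -2.28 (11 of 14 below, adjusted p = 0.037). Endoplasmic reticulum chaperones were higher in PC3 than in 22Rv1 by 1.55 (14 of 15 above, adjusted p = 0.0126 with an estimated correlation). Cholesterol synthesis genes were higher in PC3 than in 22Rv1 by 0.93 (13 of 19 above, adjusted p = 0.0126 with an estimated correlation). Proteasome subunits were lower in PC3 than in 22Rv1 by -0.65 (24 of 31 below, adjusted p = 0.0377 with an estimated correlation), though the 22Rv1 call was lost when either DMSO library was left out. Cholesterol synthesis genes were lower with the inhibitor than with the knockdown in 22Rv1 by -0.68 (5 of 20 below, camera adjusted p = 1.32e-06, 0.0825 with an estimated correlation), and here too the 22Rv1 inhibitor call was lost when either was left out.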

How the results depend on the processing

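COPS5 kept its direction and its call with shCSN5 in all 4 lines under every alternative run. Without single libraries its log2 fold change ran from -4.88 to -4.19 in LNCaP, -3.64 to -3.47 in C4-2, -2.78 to -2.58 in 22Rv1 and -3.34 to -3.14 in PC3. The change of COPS5 in LNCaP inhibitor libraries, 0.11 and not called, was -8e-04 with total counts, a scaling that moved the median of all genes there to -0.10.

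Calls of at least 2-fold, a stricter rule on the same fits, numbered 2705 in LNCaP, 1662 in C4-2, 1914 in 22Rv1 and 917 in PC3 with shCSN5, 3443, 2559 and 3588 in LNCaP, 22Rv1 and PC3 with CSN5i-3, and 5228 between the C4-2 pairs. The overlap of calls in the same direction, summed over pairs of comparisons, went from 26678 to 7616. With no low-count filter the count was 3139 in C4-2 and 4273 in PC3 with shCSN5, and 2028 for knockdown against inhibitor in 22Rv1; the cause was not tested.

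A block for replicate number gave 8180 genes in PC3 with shCSN5 (2578 without the block). For CSN5i-3 it gave 2750 over lines (5774 without) and 4919 for the difference between lines (8671 without). For knockdown against inhibitor it gave 19 in 22Rv1 (730 without) and 10074 in PC3 (6559 without). Here too the cause was not tested. Replicates share only a number: the correlation across genes of the 2 replicate differences, which pairs would make positive, ran from -0.94 in 22Rv1 with CSN5i-3 to 0.90 in PC3 with shCSN5. A spread shared by the experiment gave 4522 genes in PC3 with shCSN5, 6526 in 22Rv1 and 7885 in PC3 with CSN5i-3. The inhibitor fit was also limited to symbols found once in every table of that experiment, so its gene set changed too. The part of the spread in these counts was not separated. With an estimated correlation camera called 0 of the 268 list tests of the 8 comparisons, where 38 had an unadjusted p under 0.05. That test rests on the residual degrees of freedom, 2 in each comparison, so it could hardly call a list after adjustment. Its outcome therefore cannot decide whether correlation between genes made the preset calls. Only differences between lines or experiments were called under it, in fits with more libraries and more residual degrees of freedom.

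Leaving out each library in turn gave 2109 to 11209 genes with shCSN5 in LNCaP, 3023 to 3556 in C4-2, 4206 to 7878 in 22Rv1 and 868 to 4750 in PC3. With CSN5i-3 it gave 6242 to 11380 in LNCaP, 2990 to 5800 in 22Rv1 and 11837 to 12133 in PC3, and 9803 to 11340 between the C4-2 pairs. Over lines it gave 5567 to 6407 with shCSN5 and 4535 to 5689 with CSN5i-3, and for the difference between lines 5871 to 8905 and 7057 to 10046. Knockdown against inhibitor gave 1490 to 7931 in LNCaP, 43 to 1494 in 22Rv1 and 4352 to 8144 in PC3, and the list calls numbered 122 to 128. In LNCaP with shCSN5 the count rose when either shCSN5 library, the group with the widest replicate difference, was left out; the cause of the other shifts was not tested.

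Of the named gene values, DESeq2 kept 813 and lost 28, its size factors in edgeR kept 835 and lost 6, total counts kept 824, lost 16 and turned 1, no low-count filter kept 829 and lost 12, the block kept 812 and lost 29, the shared spread kept 792 and lost 25, and leaving out libraries kept 3049, lost 314 and gained 1. Of the list calls, size factors and total counts each kept 115 and lost 1, the block kept 110 and lost 6, and leaving out libraries kept 451 and lost 13. Chosen after seeing the data, a fit of 22Rv1 and PC3 alone gave 4462 genes for CSN5i-3 over lines and 6174 for the difference. With total counts 39.8% of called genes were higher in LNCaP with CSN5i-3 and between the C4-2 pairs. In PC3 with shCSN5 73.7% of called genes were then higher, against 61.5% with TMM and 48.7% with DESeq2. Of simulated 1.5-fold changes 1.5% were called in LNCaP with shCSN5 and 80.6% in PC3 with CSN5i-3. These comparisons differ in both spread and depth, whose parts were not separated. A small change not called in LNCaP is therefore not shown to be absent.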

Other observations

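The genes named here were chosen only after their values were seen, while the tests are those fixed before. AHR, the aryl hydrocarbon receptor, rose in the 7 comparisons with settled labels: with shCSN5 by 2.61 ± 0.19 in LNCaP, 1.43 ± 0.13 in C4-2, 1.25 ± 0.099 in 22Rv1 and 1.24 ± 0.11 in PC3, and with CSN5i-3 by 2.24 ± 0.12, 2.17 ± 0.16 and 0.99 ± 0.028 in LNCaP, 22Rv1 and PC3. TIPARP, a target gene of this receptor that also limits it, rose in the same 7, from 0.93 ± 0.13 in C4-2 with shCSN5 to 2.35 ± 0.098 in 22Rv1 with shCSN5. CYP1A1, another target gene, rose most in LNCaP with CSN5i-3 (4.32 ± 0.15) and did not pass in PC3 with shCSN5 (1.09 ± 0.37, adjusted p = 0.098). Between the C4-2 pairs AHR was higher by 3.06 ± 0.20 and TIPARP by 2.57 ± 0.12 in the pair titled C5i, while CYP1A1 was at -0.03 ± 0.16. CYP1B1, a further target gene, did not follow throughout. It rose with shCSN5 by 4.21 ± 0.42 in PC3, 2.02 ± 0.12 in 22Rv1 and 1.06 ± 0.15 in C4-2. With CSN5i-3 it rose by 3.24 ± 0.20 in PC3 but did not pass in 22Rv1 (0.16 ± 0.20, adjusted p = 0.59). Between the C4-2 pairs it was at -2.91 ± 0.21. ELF3 rose in all 7, from 1.37 ± 0.034 in PC3 to 3.03 ± 0.066 in LNCaP, both with CSN5i-3, and in PC3 it rose more with shCSN5 (2.75 ± 0.19, adjusted p of the difference = 0.00082). KLF4, a transcription factor of epithelial differentiation, rose in all 7 as well, from 0.86 ± 0.15 in C4-2 with shCSN5 to 2.08 ± 0.16 in 22Rv1 with CSN5i-3.

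In PC3 with CSN5i-3, 3 genes that act in antigen presentation rose, B2M by 1.27 ± 0.021, TAP1 by 1.44 ± 0.027 and HLA-B by 1.64 ± 0.026, with the transcription factor IRF1 at 1.88 ± 0.03. Of the other lines, in LNCaP with CSN5i-3 B2M was at 0.79 ± 0.073, TAP1 at 1.37 ± 0.076, HLA-B at 1.44 ± 0.096 and IRF1 at 2.95 ± 0.094, and between the C4-2 pairs they were at 1.58 ± 0.072, 2.37 ± 0.08, 1.85 ± 0.079 and 3.34 ± 0.10. In 22Rv1 with CSN5i-3 none of the 4 passed (0.39 ± 0.16, 0.01 ± 0.17, 0.6 ± 0.28 and 0.35 ± 0.21, adjusted p from 0.12 to 0.99). In PC3 each of the 4 rose more than with shCSN5, where the largest of the 4 changes was 0.78 ± 0.15 for IRF1 (adjusted p of the differences from 0.00016 to 4e-04). The interferon genes IFNB1 and IFNL1 went from 9 to 70 counts and from 4 to 41 counts over the 2 libraries of a group in PC3 with CSN5i-3. They reached only 0.793 and 0.466 CPM, and neither passed the interaction test of inhibitor against knockdown. MYC rose in PC3 with CSN5i-3 by 1.13 ± 0.03 and fell by 1.51 ± 0.088 in LNCaP, and was at -1.38 ± 0.21 in 22Rv1, a difference between lines at adjusted p = 8.7e-06. PTPRC, a leukocyte marker, had 3 and 5 counts in the PC3 libraries with DMSO. With CSN5i-3 it had 10 and 8 counts, no more than 0.21 CPM. With shCSN5 in PC3 it rose from 0.504 to 2.38 CPM (2.23 ± 0.22). The interaction test of inhibitor against knockdown did not pass in PC3 (-0.83, adjusted p = 0.36).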
